A study of Mus musculus with 4 samples.

How the data were processed

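Gene expression was measured by strand-specific RNA-seq of total RNA from neurosphere cultures of mouse neocortical progenitors. Per the labels' protocols, cultures were pooled within genotype, ribosomal RNA was depleted, and reads of 75 bases were taken from 4 libraries multiplexed in 1 lane, with a mean of 39300000 reads passing the instrument's filter per library. Per the submitters' processing notes, the tools were FastQC 0.10.1, Picard 1.119, SAMtools 0.1.19, STAR 2.3.0 and DESeq 1.12.1, with no role given for each. The genome build, annotation, counting rule and filter are not given in the sources used here, so no coordinates are given and genes are named by the symbols in the table.

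The deposited values are a signal per feature: the authors divided read counts by 1 factor per library. In each library every value is a whole multiple of 1 step (100% of values whole within 0.01 of a step), so whole reads could be recovered. In WT 2 the smallest value is 2 steps, and its step was taken from the spacing between values; an automatic test that takes the smallest value as 1 read does not find it. The steps correspond to factors of 0.733, 0.873, 1.64 and 0.957 for WT 1, WT 2, KO 1 and KO 2, whereas median-of-ratios factors computed from the recovered reads are 0.711, 2.16, 1.17 and 0.557. The deposited values are therefore not on a common scale: library totals differ 4.10-fold, and the median log2 fold change of all features is -1.25 as deposited and 0.012 after TMM scaling. The table holds 11160 features, of which 1110 have no symbol, 134 carry more than 1 symbol and 50 symbols occur on more than 1 feature. No feature is at 0 in either WT library, while 16 are at 0 in KO 1 and 56 in KO 2. KO 1 has such features although more reads were recovered from it (10936719) than from WT 1 (7109365). The filter behind the table is not given, so features expressed only in the KO-labelled libraries may be absent. Features without a symbol took 11.9%, 12.7%, 13.9% and 21.8% of the reads in WT 1, WT 2, KO 1 and KO 2, and the 10 most abundant features took 12.7%, 12.9%, 13.5% and 21.0%. A level of 3 reads corresponds to 0.422, 0.134, 0.274 and 0.502 CPM in these libraries; such limits cover counting error only.

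The test fixed before the data were examined was edgeR's quasi-likelihood test for counts, or limma on log2(value + 1) for normalized values. Since the deposited values are normalized, limma was used; the step of dividing them by TMM factors first was added after the files were seen, because the values were not on a common scale. Before this choice was final, limma, limma-voom, both edgeR tests and DESeq2 had been run and their results seen; the test that had been fixed was kept. Values were scaled by TMM (edgeR 4.0.16), features were kept by filterByExpr with a minimum count of 10 on the scaled values (10959 features), and limma 3.58.1 with a mean-variance trend was fitted to log2(scaled value + 1) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change is thus on the log2(value + 1) scale, which understates changes of genes with low values. CPM stands for counts per 1000000, taken for all 4 libraries over the mean of their scaled totals.

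There were 34 gene lists, fixed before the data were examined, on the cell cycle, DNA damage and survival, metabolism, stress, cell types and sample checks. The 28 lists with at least 3 measured members were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, adjusted over lists. The planned Fisher test of called genes in the lists was not run, since limma called no gene. The genes named are Mcph1, the 10 genes with the smallest p that carry a proper symbol (5 unnamed or numbered features ranked among them), and up to 4 members of each list with the smallest p; the larger sets foreseen for genes past the threshold were empty. Results of 4 list members that this rule picks were left out after the analysis, also from the counts over alternatives, for reasons unrelated to their values. Alternatives were other scalings, filters, pseudocounts and thresholds, limma-voom, DESeq2 1.42.0, edgeR's exact and quasi-likelihood tests on recovered reads, a replicate block, each library left out, histone, ribosomal protein and mitochondrial genes left out, and the trend with transcript length and GC content removed. Length and GC content were those of 1 transcript per gene symbol in GENCODE M21, the longest one, with coding transcripts preferred. They were found for 89.7% of the tested features.

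The same functions were tested on 10 simulated data sets of 11160 features with the means, library sizes and dispersions of this comparison. Each data set held 100 genes changed 2-fold and 100 changed 4-fold. Of genes changed 4-fold, limma called 83.6%, edgeR's quasi-likelihood test 85.1% and DESeq2 89.4%, and of genes changed 2-fold they called 9.8%, 10.1% and 20.1%, with means of 9.8, 10.2 and 21.7 false calls per data set. At the preset correlation, camera called a planted list of 50 genes shifted by -0.4 in 10 of 10 data sets and 0 of 200 unchanged lists; the simulated genes were independent, which real genes are not.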

Results

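RNA-seq was done on neural progenitor cells from the mouse neocortex, taken from C57BL/6J embryos at embryonic day 12.5 and expanded as neurospheres, free-floating balls of dividing progenitors. There were 4 libraries, 2 from wild-type (WT) cultures and 2 labelled as knockout of Mcph1, the gene for microcephalin, a protein that restrains chromosome condensation and whose loss causes primary microcephaly in people. Each library pooled RNA from several cultures of 1 genotype, each started from a single embryo, and all 4 were sequenced in the same lane. Because the pools are the replicates, the p-values of single genes are set against the spread between pools. Those of camera at the preset correlation compare the genes of a list with other genes, taken as nearly independent. They do not measure the spread between pools. The deposited table listed 11160 expressed features, and the reads recovered from its values came to 7109365 for WT 1, 22347416 for WT 2, 10936719 for Mcph1 KO 1 and 5975471 for Mcph1 KO 2. Levels are given as scaled CPM, that is, deposited values brought to a common scale. The design asks which genes, and in particular which genes of cell cycle progression and cell survival, differ in expression when Mcph1 is inactivated.

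The targeted gene differed little between the genotypes and was not called. Mcph1 (feature GSMG0037052) stood at 21.1 and 21.6 CPM in the WT libraries and at 19.5 and 20.3 CPM in the libraries labelled Mcph1 KO. The log2 fold change was -0.10 (SE 0.24, 95% interval -0.68 to 0.48, adjusted p = 0.921 by limma). The labels do not say which part of the gene was deleted. A count over the whole gene cannot show a missing exon, so this value does not check the knockout label. For that reason the second group is called the KO-labelled libraries. Every direction given here is KO-labelled against WT. Angpt2, which encodes angiopoietin 2 and lies inside an intron of Mcph1, differed between the KO-labelled libraries. It stood at 7.05 CPM in KO 1 and 49.1 CPM in KO 2, against 36.4 and 46.7 CPM in WT. Between genotypes it was not called (log2 fold change -1.14, SE 0.82, adjusted p = 0.722 by limma). It was among 1089 features that differed more than 2-fold between KO 1 and KO 2.

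Genes of mitosis, DNA replication, oxidative phosphorylation and the ribosome lay lower as groups in the KO-labelled libraries, by medians of 0.35 to 0.58 on the log2 scale. These 4 lists were called at a preset correlation between genes, but not with a correlation estimated from the data (adjusted p = 0.902 for each by camera). The other splits of the 4 libraries into 2 and 2 called 13 and 17 lists, against 11 for genotype. The split of WT 1 and KO 1 against WT 2 and KO 2 also called these same 4 lists, all higher in WT 2 and KO 2. Neuron markers lay higher in the library KO 1 but not in KO 2. No single gene passed the test: limma called 0 features higher and 0 lower among 10959 tested, and the smallest adjusted p was 0.631. At an unadjusted p under 0.05 there were 392 features higher and 439 lower, where 548 in all are expected by chance. The edgeR quasi-likelihood test on recovered reads also called 0 features, with 866 at an unadjusted p under 0.05. Of the other count tests, limma-voom called 0, the edgeR exact test called 7 higher and 13 lower, and DESeq2 called 6 higher and 15 lower. Both KO-labelled libraries lay above or below both WT libraries for 41.2% of features, and chance gives 33.3%. The KO-labelled libraries differed more from each other than the WT libraries did: 1089 features differed more than 2-fold between KO 1 and KO 2, and 516 between WT 1 and WT 2. Across genes, KO 2 correlated more closely with WT 1 (Pearson's r 0.961) than with KO 1 (0.942), although genes are not independent replicates.

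None of the 10 named genes with the smallest p passed in limma, where each had an adjusted p of 0.655, while DESeq2 gave each an adjusted p between 5.23e-05 and 0.0440. In the simulated data, with 100 genes changed 2-fold and 100 changed 4-fold, DESeq2 made a mean of 21.7 false calls per data set. It also called 89.4% of the genes changed 4-fold there and 20.1% of those changed 2-fold. With so many changed genes, that mean cannot be set against the calls here. The 6 DESeq2 calls higher and 15 lower are weak support for single genes, since limma, limma-voom and edgeR's quasi-likelihood test called 0. Erdr1, a gene of the pseudoautosomal region, stood at 54.9 ± 3.29 CPM in WT and 190 ± 36.9 CPM in the KO-labelled libraries (SD, n = 2 each), a log2 fold change of 1.78 (SE 0.24). Higher estimates were also found for Cnih2, an auxiliary subunit of AMPA-type glutamate receptors (1.57, SE 0.28), Lamb1, a laminin chain (1.68, SE 0.33), and Atxn2, an RNA-binding protein (1.24, SE 0.23). Lower estimates were found for Fut10, a fucosyltransferase, at 35.0 ± 0.783 CPM in WT and 11.3 ± 2.94 CPM in the KO-labelled libraries (log2 fold change -1.65, SE 0.28). Rlbp1, which encodes a retinaldehyde-binding protein, had a log2 fold change of -1.47 (SE 0.26), and Timm8a1, a chaperone of mitochondrial protein import, had one of -1.63 (SE 0.31). Tspan12, a tetraspanin of Frizzled signalling, stood at -1.39 (SE 0.27), and the ribosomal protein genes Rpl35a and Rplp2 at -1.47 (SE 0.27) and -1.21 (SE 0.24). Ribosomal protein genes have many near-identical processed pseudogenes, and Erdr1 lies in repetitive sequence, so the counts of these genes are uncertain.

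**Figure D1:**
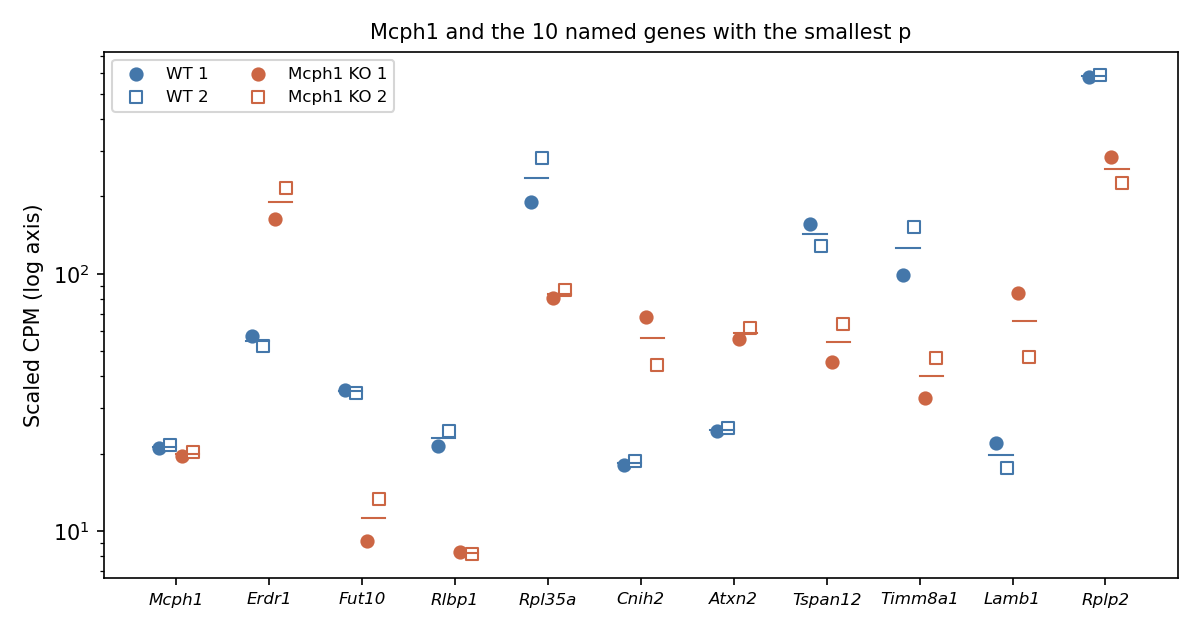
Scaled CPM (log axis) of Mcph1 and the 10 named genes with the smallest p in each of the 4 libraries, with WT in blue and Mcph1 KO in orange, circles for replicate 1, squares for replicate 2 and short lines for group means. Mcph1 lies between 19.5 and 21.6 CPM in all 4 libraries, and for each of the other 10 genes both KO-labelled libraries lie on one side of both WT libraries.

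Genes of G2/M and mitosis fell as a list (median log2 fold change -0.43, or 0.740-fold; camera on the limma fit, adjusted p = 8.31e-13, and 0.902 with an estimated correlation), with 65 of the 69 measured members lower, 48 of them with both KO-labelled libraries below both WT libraries, and 0 past the gene-wise threshold. The list of S phase and DNA replication fell by 0.35 (adjusted p = 5.70e-06, and 0.902 with an estimated correlation), with 43 of 53 members lower. Neither call thus held with a correlation estimated from the data. Among mitotic genes, Mad2l1, a spindle checkpoint protein, stood at 52.2 ± 11.1 CPM in WT and 24.7 ± 0.538 CPM in the KO-labelled libraries (log2 fold change -1.06, SE 0.25). Ccnb1, which encodes cyclin B1, stood at 251 ± 56.4 and 134 ± 5.97 CPM (-0.89, SE 0.25), and Ccnb2, which encodes cyclin B2, at 67.7 ± 5.55 and 37.7 ± 6.79 CPM (-0.85, SE 0.24). Kif18a, a kinesin that aligns chromosomes, had a log2 fold change of -0.91 (SE 0.28). Of the replication genes, Pcna, the sliding clamp of DNA polymerases, stood at 470 ± 138 CPM in WT and 248 ± 13.9 CPM in the KO-labelled libraries (-0.89, SE 0.28). Rpa3, a subunit of the single-strand binding complex, stood at -1.04 (SE 0.27), and Gmnn, which encodes the licensing inhibitor geminin, at -0.78 (SE 0.25). Rrm1, the large subunit of ribonucleotide reductase, stood at -0.74 (SE 0.25). Without WT 2, where the medians of both lists lay above WT 1, the S phase median was -0.14 and not called (adjusted p = 0.0551), and the G2/M median was -0.28 (adjusted p = 1.89e-05).

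The condensin and cohesin list, the complexes that compact chromosomes and hold sister chromatids, fell by a median of 0.26 on the log2 scale (adjusted p = 0.00471, and 0.902 with an estimated correlation), with 18 of 21 members lower. Its condensin subunits Ncapg2 (-0.64, SE 0.24) and Ncapg (-0.60, SE 0.25) and the cohesin acetyltransferase Esco2 (-0.68, SE 0.24) were lower. The cohesin loader Nipbl was higher (0.54, SE 0.24), and none of them passed. DNA damage signalling and repair fell by 0.20 (adjusted p = 0.00354, and 0.902 with an estimated correlation), with 33 of 42 members lower. Among them were the Ku subunits Xrcc6 (-0.66, SE 0.24) and Xrcc5 (-0.63, SE 0.23) and the Fanconi anaemia gene Fanci (-0.65, SE 0.24). Replication-dependent histone genes fell by a median of 0.37 (adjusted p = 0.000628, and 0.902 with an estimated correlation), with 40 of 56 members lower. The histone H4 genes Hist1h4k (-1.69, SE 0.38), Hist1h4j (-1.66, SE 0.47), Hist1h4f (-1.28, SE 0.29) and Hist1h4i (-1.18, SE 0.32) had the smallest p, and histone genes share reads with near-identical copies, so single values are uncertain. Without WT 2 the medians of these 3 lists were -0.13, -0.089 and 0.16, without KO 2 they were -0.34, -0.14 and -0.11, and none of the 3 was called in either case. With the trend of length and GC content removed, the histone list was not called either (adjusted p = 0.0514).

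Survival genes were not called as lists. Among 34 measured p53 target genes, 21 had higher and 13 lower estimates (median log2 fold change 0.14, adjusted p = 0.763), and among 32 apoptosis genes 15 were higher and 17 lower (median -0.056, mean 0.0093, adjusted p = 0.906). Gadd45a, a growth arrest gene induced by p53, stood at 3.89 and 3.89 CPM in WT and at 6.54 and 10.3 CPM in the KO-labelled libraries (1.06, SE 0.37). The p53 target Sesn1 stood at -0.54 (SE 0.22), Trp53inp1 at -0.49 (SE 0.23) and Plk3, a stress-responsive kinase, at 0.60 (SE 0.32). In the apoptosis list, Dapk1, a death-associated kinase, had a log2 fold change of 0.75 (SE 0.23), Cycs, which encodes cytochrome c, -0.75 (SE 0.29), and the pore-forming protein Bax -0.36 (SE 0.25). None of these 7 genes passed. The p53 median was 0.35 without KO 1 (adjusted p = 0.0123) and -0.071 without KO 2. Negative regulators of the cell cycle (18 genes, median -0.17, adjusted p = 0.350) and centrosome and microcephaly genes (36 genes, median -0.029, adjusted p = 0.742) were not called either.

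Ribosomal protein genes fell by a median of 0.58 on the log2 scale (0.667-fold, adjusted p = 2.18e-20, and 0.902 with an estimated correlation), with 74 of 75 members lower, 0 past the threshold over all genes and 8 lower when adjusted over the list alone. Rps25 stood at 676 ± 29.4 CPM in WT and 288 ± 67.9 CPM in the KO-labelled libraries (-1.25, SE 0.26), Rps27a at -1.26 (SE 0.29) and Rpl37a at -1.04 (SE 0.24). Nuclear-encoded genes of oxidative phosphorylation fell by 0.37 (adjusted p = 1.16e-09, and 0.902 with an estimated correlation), with 68 of 78 lower. Among them were the complex I subunits Ndufb3 (-0.85, SE 0.24), Ndufs6 (-0.84, SE 0.24), Ndufa2 (-0.73, SE 0.24) and Ndufc1 (-0.72, SE 0.22). Genes of pyruvate, glutamine and the TCA cycle fell by 0.24 (32 of 40 lower, adjusted p = 0.00354, and 0.902 with an estimated correlation), with Suclg2 at -0.79 (SE 0.25) and Idh2 at -0.63 (SE 0.24), both mitochondrial enzymes of that cycle. Cholesterol biosynthesis fell by 0.32 (20 of 23 lower, adjusted p = 0.000684, and 0.902 with an estimated correlation), with the isomerase Idi1 at -1.14 (SE 0.32) and the farnesyl diphosphate synthase Fdps at -0.91 (SE 0.31). Without KO 1 the oxidative phosphorylation and TCA medians were -0.14 and -0.038 and neither was called, and the TCA list was not called without WT 1 either (-0.12, adjusted p = 0.117). Over the libraries left out in turn, the ribosomal protein median ranged from -0.82 to -0.39 and the cholesterol median from -0.42 to -0.17, and both kept their call. Transcript length moved with these groups: across genes the log2 fold change rose with length (Spearman's rho 0.263), from a median of -0.25 for transcripts of 500 to 1000 bases to 0.17 for those over 6000. In the class under 500 bases (-0.32) only WT 2 lay high, and WT 1 lay below both KO-labelled libraries. Length also separated the KO-labelled libraries from each other (rho 0.170 for KO 1 minus KO 2): from the class of 500 to 1000 bases to that over 6000, the medians went from -0.36 to 0.22 in KO 1 and from -0.14 to 0.11 in KO 2. Ribosomal and respiratory chain genes have short transcripts.

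**Figure D2:**
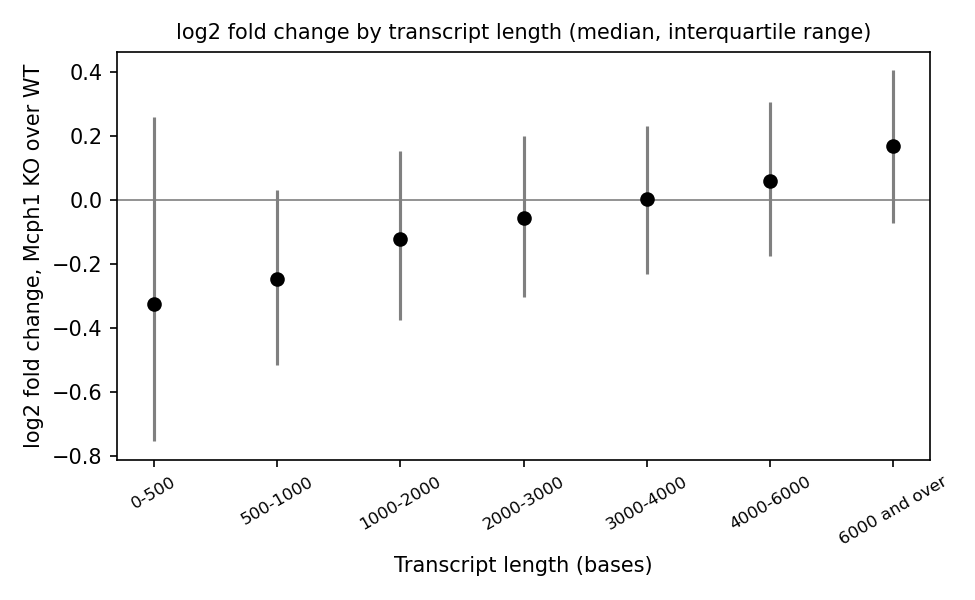
Log2 fold change (KO-labelled over WT) against transcript length in bases, with points for the median over genes and vertical lines for the interquartile range. The medians go from -0.32 in the shortest to 0.17 in the longest of the 7 length classes, and the shortest class does not separate the groups.

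Neuron markers rose as a list (median log2 fold change 0.61, adjusted p = 0.0107; 16 of 18 members higher, 0 past the gene-wise threshold; adjusted p = 0.902 with an estimated correlation). Of the 32 genes on this list, 18 were measured, and members expressed only in the KO-labelled libraries may be missing from the deposited table. Relative to the WT mean, the list's median was 1.50 in KO 1 and -0.20 in KO 2. Without KO 1 the fold change was -0.20 and without KO 2 it was 1.50. Syt1, a synaptic vesicle calcium sensor, stood at 38.6 CPM in KO 1, 12.8 CPM in KO 2 and 8.19 and 7.04 CPM in WT, and Celf4, a neuronal RNA-binding protein, at 61.2, 13.0, 10.8 and 7.41 CPM. Interferon-stimulated genes also rose (median 0.70, 7 of 8 members higher, adjusted p = 0.00471, adjusted p = 0.902 with an estimated correlation), with 0.89 in KO 1 and 0.27 in KO 2, and they were not called without KO 1 (0.27) or without WT 2 (0.33, adjusted p = 0.0596). Only 8 of the 36 genes on this list were measured, among them the RNA sensor Ddx58 with a log2 fold change of 0.87 (SE 0.29).

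Radial glia and progenitor markers were not called as a list (23 genes, median 0.061, adjusted p = 0.906; camera's direction was lower), with members on both sides. Fabp7, the brain lipid-binding protein of radial glia, stood at 5347 ± 57.0 CPM in WT and 2142 ± 172 CPM in the KO-labelled libraries (log2 fold change -1.32, SE 0.31; adjusted p = 0.655 by limma and 0.00407 by DESeq2). Nes, which encodes the progenitor filament nestin, stood at -0.82 (SE 0.30), and Zbtb20 and Gli3, a pair of zinc finger transcription factors of the developing forebrain, stood at 1.26 (SE 0.34) and 1.24 (SE 0.48). The Gli3 estimate was carried by KO 1, at 39.1 CPM against 14.2 CPM in KO 2 and 9.16 and 10.8 CPM in WT, and was 0.51 without KO 1.

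**Figure D3:**
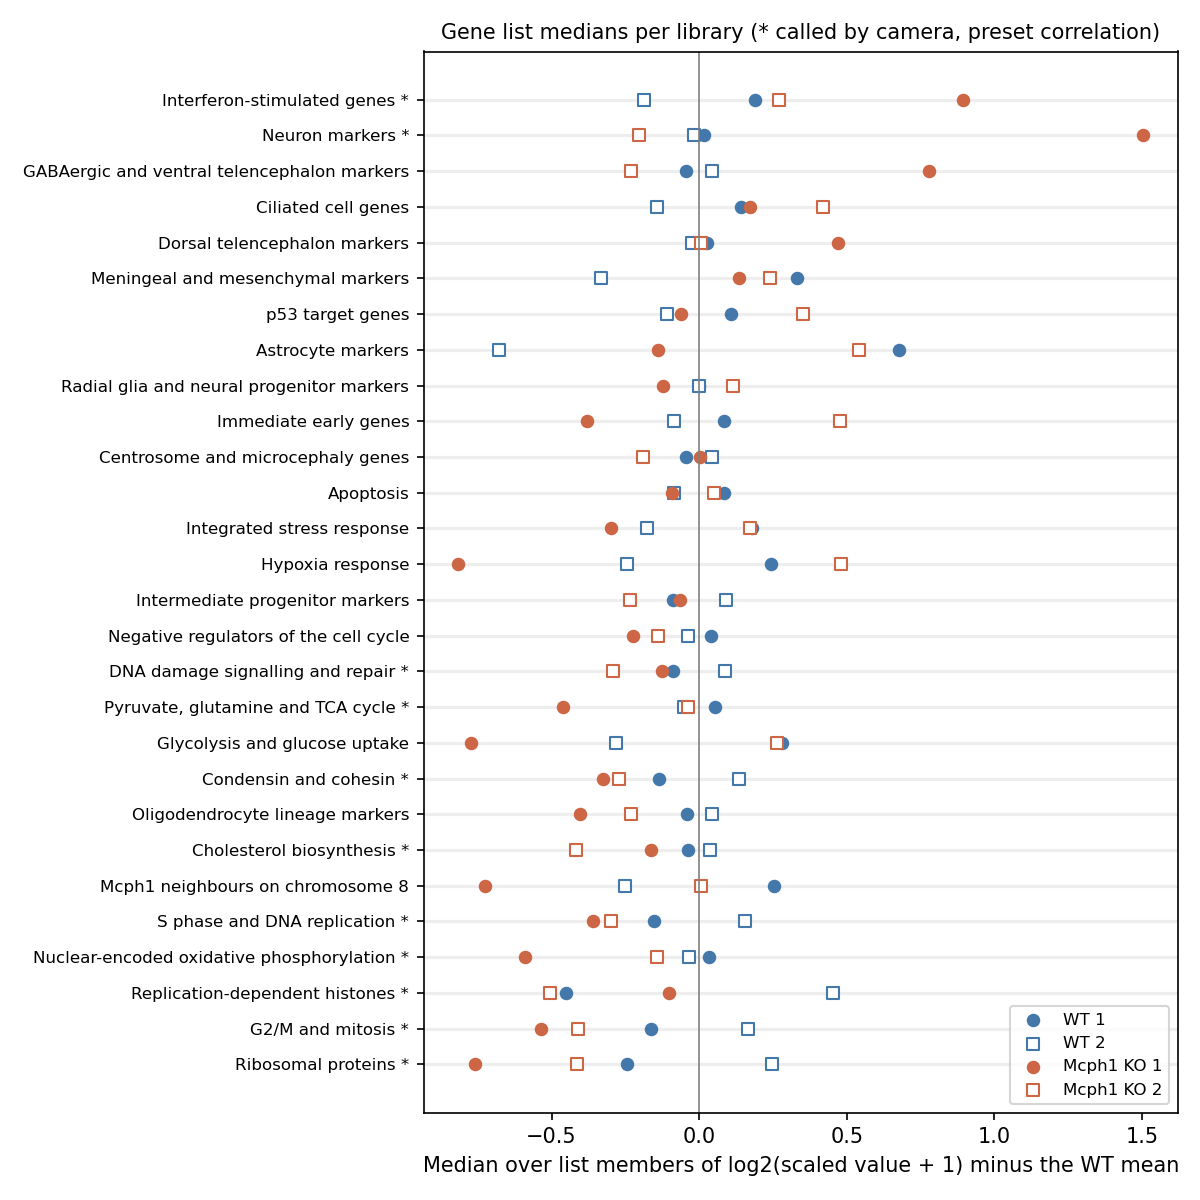
Median over the members of each gene list of log2(scaled value + 1) minus the WT mean, for each of the 4 libraries (WT in blue, Mcph1 KO in orange, circles for replicate 1, squares for replicate 2); stars mark the 11 lists called by camera at the preset correlation. Both KO-labelled libraries lie below both WT libraries for the G2/M and ribosomal protein lists, while the neuron list stands at 1.50 in KO 1 and at -0.20 in KO 2.

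In all, 11 of the 28 lists with at least 3 measured members were called at the preset correlation, 9 lower and 2 higher, but 0 were called with an estimated correlation and 0 by fry, limma's self-contained test of a set (smallest adjusted p = 0.630). At the preset correlation, camera called 13 and 17 lists when the 4 libraries were split in the other ways that put 1 WT and 1 KO-labelled library in each group. With WT 2 and KO 2 as a group, its adjusted p was 2.65e-18 for ribosomal proteins and 5.48e-08 for G2/M, which the remaining split did not call. The S phase, oxidative phosphorylation, histone and neuron lists were among those called in each of the 3 splits, so such calls are not particular to genotype. With 3 splits in all, no share under 0.05 can be reached.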

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

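The edgeR quasi-likelihood test on recovered reads without a block, the unscaled values, the crossed pairing and the removal of the length and GC trend were chosen after seeing the data, and the replicate block, planned for edgeR, was also fitted in limma. The others were fixed before. Over all alternatives, 2208 of the named genes' estimates kept their direction and side of the threshold, 45 gained a call and 19 reversed; for list medians these counts were 541, 14 and 36, and 23 lost a call. Mcph1 stayed between -0.14 and -0.059 under the alternatives and was never called; single genes and lists were not compared with the unscaled values, whose scale shifts every fold change. Between 9 and 15 lists were called under each alternative except an estimated correlation, where 0 were. Where a call changed, the cause was not tested. Leaving out a library leaves 1 in its group, assumed to vary like the other group.

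DESeq2 called 6 genes higher and 15 lower, the edgeR exact test 7 and 13, and the unscaled deposited values 6 lower. When each library was left out, the number called ranged from 0 to 110 higher and from 0 to 69 lower, with both maxima without KO 2. No label says that same-numbered libraries share a litter or batch. Their deviations correlated at -0.308 across genes, which cannot show whether they do. With the replicate block, limma called 0 genes (473 at an unadjusted p under 0.05), Mcph1 stood at -0.10 and 11 lists were called, so the block changed no call. The crossed pairing, of WT 1 with KO 2 and WT 2 with KO 1, called 0 genes in limma. It had 1481 features at an unadjusted p under 0.05, against 831 with no block, and a smallest adjusted p of 0.107, against 0.631. The libraries may thus share a structure along this pairing, which no label names.

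With an estimated correlation no list was called (adjusted p = 0.902 for each of the 11): ribosomal proteins (-0.58), G2/M (-0.43), histones (-0.37), oxidative phosphorylation (-0.37), S phase (-0.35), cholesterol (-0.32), condensin and cohesin (-0.26), TCA cycle (-0.24), DNA damage (-0.20), neurons (0.61) and interferon-stimulated genes (0.70). With the length and GC trend removed, histones stood at -0.25 and lost their call, oligodendrocyte markers gained one at -0.38, and radial glia stood at -0.0093.

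Ranges over the 4 libraries left out in turn, for lists whose call or direction changed, were -0.49 to -0.14 for S phase, -0.42 to -0.13 for condensin and cohesin, -0.29 to -0.089 for DNA damage, and -0.86 to 0.16 for histones. They were -0.60 to -0.14 for oxidative phosphorylation, -0.47 to -0.038 for the TCA cycle, 0.27 to 0.98 for interferon-stimulated genes, -0.20 to 1.50 for neurons, and -0.071 to 0.35 for p53 targets. Lists not called with all libraries ranged from -0.17 to 0.084 (apoptosis), -0.51 to 0.88 (astrocytes), -0.19 to 0.025 (centrosome), 0.0062 to 0.46 (dorsal), -0.23 to 0.77 (GABAergic) and -0.78 to 0.26 (glycolysis). The remaining ones ranged from -0.83 to 0.48 (hypoxia), -0.39 to 0.48 (immediate early), -0.31 to 0.17 (integrated stress), -0.74 to 0.0078 (neighbours of Mcph1), -0.17 to 0.42 (meningeal) and -0.13 to 0.12 (radial glia). Lists that kept their call and direction ranged from -0.60 to -0.28 (G2/M), -0.23 to -0.12 (negative regulators), -0.23 to -0.027 (intermediate progenitors), -0.42 to -0.20 (oligodendrocytes) and 0.16 to 0.50 (ciliated cells).

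Small medians changed sign with other settings. Apoptosis stood at 0.011 with DESeq2, 0.016 with the exact test, 0.011 with the quasi-likelihood test and 0.0093 as a mean. Astrocyte markers stood at -0.046, -0.040 and -0.040 with those 3 count tests, and immediate early genes at 0.073, 0.079 and 0.077, at 0.034 with upper-quartile factors and at 0.0088 with library size only. Centrosome genes stood at 0.011 with upper-quartile factors.

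Among genes whose direction changed with 1 library left out, estimates ranged from -2.54 to 0.25 (Angpt2), -0.31 to 0.022 (Ccdc39), -0.53 to 0.74 (Cspg4), -0.22 to 2.00 (Fn1), -1.60 to 0.45 (Fos), -0.040 to 1.36 (Gad1), -2.06 to 0.51 (Ier3) and -0.24 to 0.63 (Jun). Others ranged from -0.012 to 0.81 (Lhx2), -0.25 to 0.32 (Notch3), -1.12 to 0.063 (P4ha1), -0.78 to 3.98 (Sst), -0.85 to 1.92 (Ttr), -0.92 to 0.067 (Vldlr), -0.12 to 0.66 (Wnt7b) and -0.55 to 0.12 (Xist). Genes of the report that kept their direction but moved by over 1.5 times ranged from -1.19 to -0.59 (Pcna), -0.82 to -0.39 (Ncapg), -2.36 to -0.98 (Hist1h4j), 0.29 to 0.91 (Plk3), -1.04 to -0.46 (Cycs), -0.56 to -0.16 (Bax) and -1.56 to -0.72 (Idi1). The same holds for Fdps (-1.27 to -0.56), Pgk1 (-1.68 to -0.28), Nes (-1.11 to -0.54), Gli3 (0.51 to 1.95), Syt1 (0.75 to 2.32) and Celf4 (0.53 to 2.75).

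In simulated data with these library sizes, dispersions and 2 libraries per group, limma called 9.8% of genes changed 2-fold and 83.6% of those changed 4-fold. Each simulated data set held 100 genes of each kind, and its genes were independent. These shares therefore do not say what limma would call where fewer genes change.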

Other observations

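The tests of transcript length and GC content were added after the fold changes had been seen, and the test of the neuron share in KO 2 was chosen after its result was known; the second neuronal list was written after the first list had been seen and before its own values were.

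Several lists that the test did not call between the genotypes stood apart in 1 library or split the libraries another way. Glycolysis and glucose uptake (26 genes, median log2 fold change -0.26, adjusted p = 0.191 by camera on limma) stood at -0.77 in KO 1 and 0.26 in KO 2 relative to the WT mean, and hypoxia response genes (24 genes, -0.090, adjusted p = 0.411) at -0.82 and 0.48. The glycolytic enzyme Pgk1 stood at 830 and 676 CPM in WT, 235 CPM in KO 1 and 616 CPM in KO 2, and P4ha1, a collagen prolyl hydroxylase induced by hypoxia, at 480 and 260 CPM in WT, 163 CPM in KO 1 and 369 CPM in KO 2. Astrocyte markers (19 genes, 0.13, adjusted p = 0.549) stood at 0.68 in WT 1, -0.68 in WT 2, -0.14 in KO 1 and 0.54 in KO 2. Immediate early genes (10 genes, -0.0064, adjusted p = 0.973) stood at -0.38 in KO 1 and 0.48 in KO 2, with the transcription factor Fos at 27.4 CPM in KO 1 and 113 CPM in KO 2. The integrated stress response (28 genes) had a median of -0.066 (adjusted p = 0.332).

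KO 1 also held the highest levels of Sst, an interneuron neuropeptide, at 123 CPM against 4.44 to 10.1 CPM in the other libraries, and of Ttr, the transthyretin of the choroid plexus, at 930 CPM against 136 to 271 CPM. GABAergic and ventral markers (9 genes, 0.36, adjusted p = 0.406) stood at 0.78 in KO 1 and -0.23 in KO 2, and dorsal telencephalon markers (8 genes, 0.25, adjusted p = 0.332) at 0.47 and 0.0062. Oligodendrocyte lineage markers (13 genes, -0.30, adjusted p = 0.130) were not called, with 9 members lower and 4 higher. Among them the progenitor receptor Pdgfra stood at 189 ± 7.87 CPM in WT and 89.2 ± 29.4 CPM in the KO-labelled libraries (SD, n = 2 each; log2 fold change -1.12, SE 0.29), not past the threshold, while Bcas1 stood at 67.5 and 74.0 CPM in WT and 104 and 94.4 CPM in the KO-labelled libraries. Intermediate progenitor markers (8 genes, -0.10, adjusted p = 0.677), meningeal and mesenchymal markers (6 genes, 0.19, adjusted p = 0.861, with camera's direction lower), ciliated cell genes (4 genes, 0.35, adjusted p = 0.332) and neighbours of Mcph1 (7 genes, -0.34, adjusted p = 0.332) were not called. Microglia, endothelial and choroid plexus lists had 2 measured members each, with medians of 0.64, 0.071 and 0.55, and were not tested. Xist was the 1 sex-linked gene measured (median -0.21), and the erythroid and mitochondrially encoded lists had 0 measured members.

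The first pattern is the lower level of cell cycle, ribosomal protein and oxidative phosphorylation genes. A length and GC content bias between libraries, as the whole cause, is argued against for both parts. After the trend fitted on other genes was removed, the median over 120 S phase and G2/M genes was -0.390 (95% bootstrap interval over genes -0.454 to -0.326), against -0.410 before. That over 153 ribosomal and oxidative phosphorylation genes was -0.339 (-0.398 to -0.261), against -0.489 before, so part of the latter may come from length. The longest transcript of each gene was used, which can be longer than the expressed one. The trend may thus be removed only in part for these genes. The intervals resample genes as if independent, while the estimated correlation between genes was 0.41 to 0.64 in these lists. They do not measure the spread between libraries, so the argument rests on the medians alone. A larger share of neurons, which do not divide, was also considered. In KO 2 the neuron median was -0.204 relative to WT (interval over genes -0.640 to 0.084), while its S phase and G2/M median was -0.38. These values go against it for KO 2, but they rest on a single library. The test was chosen after its result was known, so it does not settle the question. For KO 1 a larger share of neurons stays open, as do differences between culture pools and the genotype itself.

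The second pattern is the high level of neuron markers in KO 1. A length and GC bias of that library is argued against: the difference to the other 3 libraries was 1.61 before and 1.65 after removing the trend (interval 1.34 to 2.06). More RNA from neurons in that library is a candidate explanation: a second list of 31 neuronal genes was higher by a median of 1.14 (0.841 to 1.25), with 29 of them above all 3 other libraries. Both intervals are over genes, whose estimated correlation was 0.73 in the first neuron list, and do not measure the spread between libraries. Cultures with more neurons in the pool could arise with either genotype, and KO 2 does not share the pattern.

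The third pattern is the number of called gene lists. The genotype split called 11 lists, and the other splits of the 4 libraries into 2 and 2 called 13 and 17, so all 3 of 3 splits gave at least as many. With 3 splits no share under 0.05 can be reached. By features at an unadjusted p under 0.05 in limma, the split of WT 1 and KO 1 against WT 2 and KO 2 had 159 and genotype 831, each with 0 genes called. The split of WT 1 and KO 2 against WT 2 and KO 1 called the most lists, had 924 such features and called 1 gene. In it, the hypoxia, glycolysis and astrocyte lists were higher in WT 1 and KO 2 by medians of 0.82, 0.85 and 0.95. This may reflect a structure of the libraries other than genotype, and no label names a batch that follows it.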
